A study of Homo sapiens with 15 samples.

How the data were processed

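The data were 1 table of FPKM values (fragments scaled to transcript length and to the mapped fragments of the library) with 1 column per donor, deposited by the authors. The unit is given by the column names, per the file headers. The column names of all donors begin with refed3, in the NR group with refed3NR. The meaning of refed3 is not given in the sources used here, so it was not interpreted. Per the labels' protocols, CD4 T cells were negatively selected from blood mononuclear cells and cultured, total RNA was extracted with a column kit that keeps small RNA, and stranded libraries of total RNA were sequenced on an Illumina instrument. How long the cells were cultured, and whether they were stimulated, is not given in the sources used here. Per the submitters' processing notes, FastQC, Trimmomatic, HISAT2, StringTie and GRCh38 were used, with no versions; the gene annotation, the trimming and the counting settings are not given in the sources used here. The low values of the deposited FPKM do not step in whole reads, so the sequencing depth is unknown and no counting error can be given. FPKM is relative to each library's total, so a large change in a few abundant transcripts shifts all others.

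The deposited table had 10323 rows with 10322 distinct gene identifiers, 1 identifier being listed in 2 rows with the same values. Every row had 1 FPKM or more in at least 8 of the 15 samples, so genes below that level had been left out before deposit. A gene at that level only in the 7 NR donors would be absent, while one at that level only in the 8 placebo donors could be present. For such low genes a rise with NR could be missed where a fall could be seen. Symbols were found for 10303 identifiers in a table of gene names, and 10321 identifiers were found in GENCODE v29 on GRCh38, which gave the coordinates, gene types, transcript lengths and GC content. Whether the authors used that annotation is not given. 1 row had no symbol, and 44 rows of genes on chromosome Y, or on X and known to escape inactivation, were left out because the donors are people. Where a symbol had more than 1 row, the row of highest mean was used. The planned filter, 1 FPKM or more in at least 7 samples, removed 0 genes, and 10277 genes were tested. No donor's values were identical to another's; correlations between donors ran from 0.862 to 0.971.

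Groups came from the treatment given in the labels: 8 placebo and 7 NR donors. Replicate numbers only name a donor and pair nothing. Each gene was tested on log2(FPKM + 1) with limma 3.58.1 (trend and robust) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A fold change on this scale understates the change of low genes. For each gene list with at least 5 members in the table, the mean of log2(FPKM + 1) over its members was taken per donor, and the difference of group means was tested two-sided with an exact permutation test over all 6435 splits of 15 donors into 7 and 8, adjusted over 32 lists. The smallest p this test allows is 0.000155. The intervals of list differences are 95% intervals. The whole profile was compared by the share of squared Euclidean distance between groups, with the same exact permutation test.

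The lists, tests and most alternatives were set before the data were examined. Genes were named by a fixed rule. The first part took, in each direction, the 12 genes of largest fold change past the threshold, filled by smallest p where fewer passed. The second part took, in each list, up to 6 members with a p under 0.05 adjusted over the list alone, otherwise the 2 members of smallest p. The third part was a fixed set of genes of NAD metabolism, helper subsets, arginine metabolism and the NRF2 response. A few genes that the rule names are not reported here. Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean of 5 FPKM or more, TPM rescaling, median of ratios scaling, quantile normalization, leaving out each donor, a covariate for naive against effector markers, limma without trend and robust, array weights, exact permutation per gene, camera, fry, summed rows and a fold change minimum of 0.5. Removal of trends with GC content and length (natural splines with 5 degrees of freedom), rescaling to nuclear protein coding genes, a mitochondrial covariate and leaving out the 2 NR donors of highest mitochondrial share were added after the data were seen.

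The scripts were tested on simulated data made from the 10277 genes and 15 donors, with 200 genes changed. At a log2 change of 0.5, 30.0% of the changed genes were recovered, at 1 82.8%, at 1.5 93.6% and at 2 98.0%, and 4.76% of the calls were false. The noise was drawn separately for each gene, so these rates do not cover differences between donors that many genes share. In runs on shuffled residuals of the real data, which keep the correlation between genes, 7.74% of the unshifted lists had an exact permutation p under 0.05. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.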

Results

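RNA was measured in CD4 T cells from the blood of 15 healthy participants of a double-blinded trial, of whom 8 received placebo and 7 received NR. NR is taken here as nicotinamide riboside, a precursor of the coenzyme NAD; the labels give only the abbreviation. CD4 T cells are the helper lymphocytes, and they had been isolated by negative selection and kept in culture medium. Each donor gave 1 column of FPKM values, and 10277 genes were tested, of which 9165 were protein coding. The FPKM values of a donor summed to between 212507 and 304712, and the number of reads behind them is unknown, so no counting interval can be given. Protein coding transcripts of the mitochondrial genome made up 12.8% to 32.1% of that sum. The title of the series names NAD, inflammation by TH17 cells, arginine synthesis and redox control, and the comparison of the groups asks which transcripts differed between donors who took NR and donors who took placebo.

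Only 2 of the 10277 genes passed an adjusted p of 0.05 with limma. SNHG19, a small nucleolar RNA host gene that makes a long non-coding RNA (chromosome 16, 2154797 to 2155358, minus strand, GRCh38), rose from 6.36 ± 1.12 FPKM in placebo (SD, n = 8) to 13.6 ± 3.44 FPKM with NR (SD, n = 7). Its log2 fold change on the log2(FPKM + 1) scale was 0.97 (SE 0.15, adjusted p = 0.042), and all 7 NR donors lay above every placebo donor. PARGP1, a transcribed pseudogene of the poly(ADP-ribose) glycohydrolase gene PARG (chromosome 10, 45854093 to 45972154, minus strand), fell from 2.49 ± 0.71 to 0.98 ± 0.14 FPKM, with a log2 fold change of -0.79 (SE 0.13, adjusted p = 0.042). All 7 NR donors lay below every placebo donor. PARGP1 ran from 0.78 to 1.13 FPKM in NR donors and was at 1.48 or more in placebo donors. It could thus have entered a table cut at 1 FPKM through the placebo donors alone. A low gene that rose in the same way could be absent. PARGP1 is a near copy of PARG, so its level is uncertain where the counting split shared reads. By an exact permutation test of each gene, 1732 genes had an unadjusted exact p under 0.05; that test cannot call 2 genes over the whole table, since at least 32 must pass together. With TPM scaling PARGP1 passed and SNHG19 did not (adjusted p = 0.102), with GC and length trends removed SNHG19 passed and PARGP1 did not (adjusted p = 0.115), and with median of ratios scaling or quantile normalization neither did. Where the call was lost, the log2 fold change of SNHG19 was 0.91 with TPM and 1.02 with median of ratios and with quantile normalization. That of PARGP1 was -0.70 with trends removed, -0.75 with median of ratios and -0.77 with quantile normalization. The count also depended on single donors. It was 0 without any of 11 donors, 1 without placebo replicate 1 or NR replicate 6, 8 without placebo replicate 2 and 364 without NR replicate 1, and it was 883 with array weights.

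**Figure D1:**
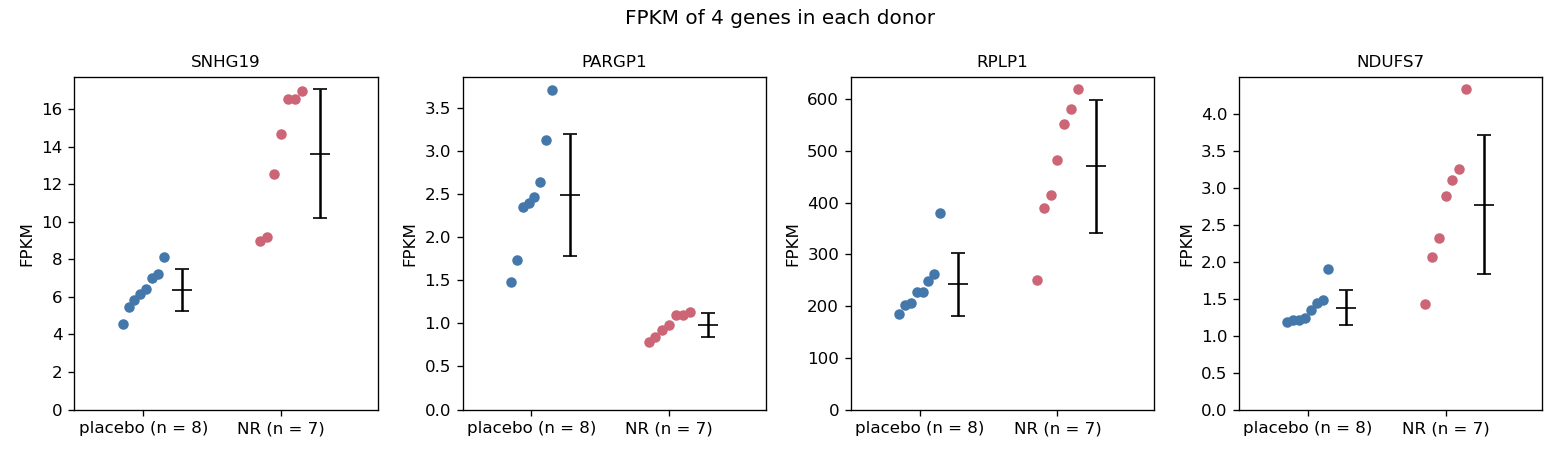
FPKM of SNHG19, PARGP1, RPLP1 and NDUFS7 in each donor (points), with placebo (n = 8) and NR (n = 7) on the horizontal axis; the bar is the mean ± SD of the group. SNHG19 and PARGP1 do not overlap between the groups, while RPLP1 and NDUFS7 overlap and did not pass the threshold over all genes.

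Below the threshold, 1737 genes (16.9%) had an unadjusted p under 0.05, against 514 expected by chance, and 673 of them (38.7%) were higher with NR. The share that was higher moved with the scaling: 13.1% after rescaling to TPM, 26.0% after rescaling to nuclear protein coding genes, 49.6% after quantile normalization, 55.1% after scaling by the median of ratios and 52.3% after removing trends with GC content and length. TPM shifted the median log2 fold change of all genes from -0.04 to -0.18. In 18 genes (0.175%) the groups did not overlap, where the mean rate by chance is 0.0311%. This rate and the 514 above are means and leave out how far such counts spread by chance. Over 99 other splits of the donors into groups of the same sizes, the count at an unadjusted p under 0.05 had a median of 294. Its 95th percentile was 1321. The 18 genes were not set against other splits, so whether they exceed chance was not tested. Of the 1737 genes, 939 also had an unadjusted p under 0.05 with GC and length trends removed. Without the 2 NR donors of highest mitochondrial share, where fewer samples were tested, 855 did. The genes that followed SNHG19 and PARGP1 by p all had an adjusted p of 0.116. GZMM, a granzyme of cytotoxic lymphocytes, was at 7.16 ± 2.06 FPKM in placebo and 19.7 ± 8.71 with NR. RPLP1, a protein of the large ribosomal subunit, was at 242 ± 60.8 and 470 ± 128 FPKM. The other genes on the higher side were SLC2A4RG, FBXW5, EIF4EBP3, TSR3, PVRIG, EID1, FAM174A, LINC01003 and the mitochondrial tRNA gene MT-TQ, with log2 fold changes from 0.59 for FAM174A to 1.58 for MT-TQ. On the lower side, B4GALT4 was at 5.81 ± 1.13 and 3.30 ± 0.66 FPKM, CASP10, an initiator caspase, at 3.50 ± 0.62 and 1.96 ± 0.41 FPKM, and MGA, a transcription factor that binds MAX, at 7.02 ± 1.18 and 4.37 ± 0.74 FPKM. POMK, SUDS3P1, LINC01891, SUCO, NPTN-IT1, NOL9 and the T cell receptor joining segments TRAJ22 and TRAJ20 had log2 fold changes from -0.49 for NOL9 to -0.96 for TRAJ22.

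Of the 37 gene lists fixed before the data were examined, 32 had at least 5 members in the table, and 0 passed an adjusted p of 0.05 by the exact permutation test of the list mean; 2 had an unadjusted p under 0.05. Fry called 0 lists by direction and 1 list for change in either direction. Nuclear genes of oxidative phosphorylation had the smallest p. Their mean was higher with NR by 0.20 on the log2 scale (95% interval 0.07 to 0.32, exact permutation p = 0.00575, adjusted p = 0.184). In this list, as in the antioxidant and Th17 lists given below, 7 of 7 NR donors lay above the placebo median. Of the 76 members, all tested, 65 had a positive fold change and 8 had a p under 0.05 adjusted over the list alone, but 0 passed over all genes. COX8A, a subunit of cytochrome c oxidase, was at 50.1 ± 12.3 FPKM in placebo and 80.8 ± 14.99 with NR. NDUFS7 and NDUFB7, subunits of complex I, had log2 fold changes of 0.63 (SE 0.14) and 1.04 (SE 0.27), UQCR11 of complex III 0.57, NDUFA3 0.48 and NDUFA11 0.54. Under TPM scaling the list's difference was 0.08 (exact permutation p = 0.296). It was 0.26 with median of ratios scaling (exact permutation p = 0.00513, adjusted p = 0.141) and 0.24 with quantile normalization (exact permutation p = 0.00544, adjusted p = 0.174). Rescaling to nuclear protein coding genes gave 0.15 (exact permutation p = 0.00513, adjusted p = 0.164).

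Cytosolic ribosomal protein genes were higher with NR by 0.30 (95% interval 0.03 to 0.57, exact permutation p = 0.0322, adjusted p = 0.515). The difference was 0.16 with TPM scaling (exact permutation p = 0.144) and 0.11 with quantile normalization (exact permutation p = 0.108). It was 0.37 with median of ratios scaling (exact permutation p = 0.0294, adjusted p = 0.235). Rescaling to nuclear protein coding genes gave 0.245 (exact permutation p = 0.0455, adjusted p = 0.718). Of 76 members 75 had a positive fold change, and 20 had a p under 0.05 adjusted over the list alone, with 0 over all genes. RPS28 was at 109 ± 26.2 FPKM in placebo and 213 ± 75.3 with NR, RPL36 at 123 ± 32.8 and 209 ± 59.5, RPS16 at 234 ± 41.2 and 336 ± 67.7, and RPL13A at 777 ± 125 and 1116 ± 242 FPKM. The 13 protein genes encoded in mitochondrial DNA differed by 0.42 (95% interval -0.17 to 1.01, exact permutation p = 0.145), all with a positive fold change; MT-ND6 was at 51.02 ± 19.8 and 99.98 ± 43.8 FPKM, and MT-ATP6 had a log2 fold change of 0.50. Antioxidant enzymes differed by 0.11 (95% interval -0.0017 to 0.22, exact permutation p = 0.0527) and by -0.0081 with TPM scaling. Of the 25 members tested, 4 had a p under 0.05 adjusted over the list alone. These were GPX4, the glutathione peroxidase that acts on lipid peroxides (24.2 ± 3.07 and 34.6 ± 6.52 FPKM), and the mitochondrial proteins GLRX5, PRDX5 and TXN2, with log2 fold changes of 0.42, 0.45 and 0.32. Camera with a preset correlation of 0.01 called these 4 lists. With an estimated correlation it called 0 (adjusted p = 0.781 with an estimated correlation for oxidative phosphorylation and 0.934 for each of the other lists). Across genes, which are not independent replicates, the log2 fold change had a rank correlation of 0.331 with transcript GC content. With GC and length trends removed, the oxidative phosphorylation list differed by 0.23 (exact permutation p = 0.00373, adjusted p = 0.119). The ribosomal list then differed by 0.35 (exact permutation p = 0.0247, adjusted p = 0.264).

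**Figure D2:**
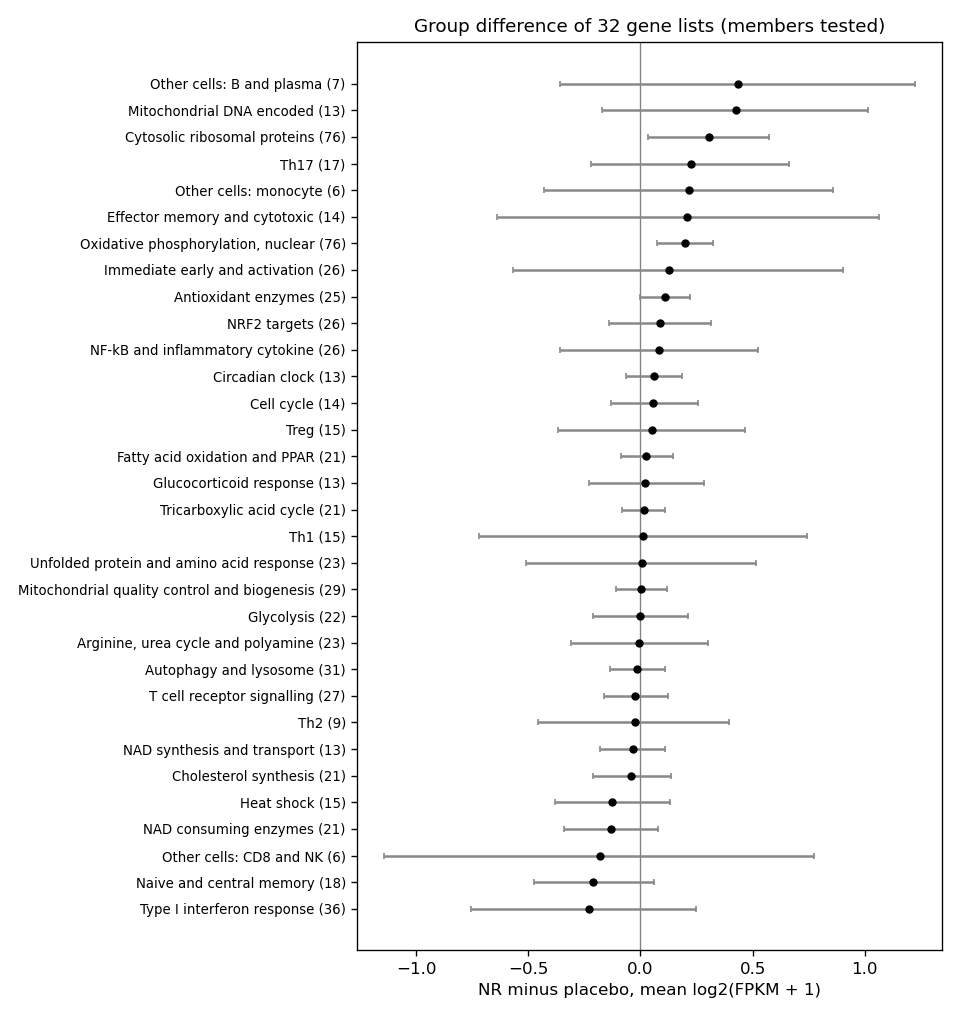
Difference of the group means of log2(FPKM + 1), NR minus placebo, for each of 32 gene lists (points) with its 95% interval (bars); the number of members tested stands in parentheses. Only the intervals of oxidative phosphorylation (0.07 to 0.32) and of cytosolic ribosomal proteins (0.03 to 0.57) lie above 0, and neither list passed after adjustment.

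Genes of NAD synthesis and transport differed by -0.03 (95% interval -0.18 to 0.11, exact permutation p = 0.617, 13 members tested). NAMPT, the rate-limiting enzyme of NAD salvage, was at 9.16 ± 3.11 FPKM in placebo and 9.10 ± 3.38 with NR. NMRK1, the kinase that phosphorylates nicotinamide riboside, was at 9.83 ± 2.94 and 11.9 ± 4.37, NAPRT at 2.76 ± 1.47 and 3.39 ± 1.33, and SLC25A51, the mitochondrial NAD carrier, at 3.61 ± 0.58 and 2.91 ± 0.51 FPKM. The log2 fold change of NNT was -0.30. Of the 25 genes listed for NAD synthesis and transport, 13 were in the table, and NMNAT1 was not among them. Enzymes that consume NAD differed by -0.13 (95% interval -0.34 to 0.08, exact permutation p = 0.183), and 2 of 21 members had a p under 0.05 adjusted over the list alone. PARP14 was at 14.6 ± 5.79 FPKM in placebo and 7.73 ± 1.05 with NR, and SIRT6, a nuclear sirtuin, at 2.22 ± 0.57 and 3.48 ± 0.54. SIRT1 (17.5 ± 2.99 and 16.4 ± 3.05), SIRT3 (2.71 ± 0.86 and 2.69 ± 0.56, log2 fold change 0.0082), CD38 (3.27 ± 1.22 and 3.30 ± 1.29) and PARP1 (18.8 ± 4.69 and 15.5 ± 5.07) differed by less than the spread between donors.

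Genes of the Th17 programme, the helper subset that makes interleukin 17, differed by 0.23 (95% interval -0.22 to 0.66, exact permutation p = 0.275), with 0 of 17 members past 0.05 adjusted over the list alone. IL17A was at 4.71 ± 8.16 FPKM in placebo and 4.97 ± 4.50 with NR, the nuclear receptor RORA at 11.9 ± 7.19 and 14.999 ± 3.43, and the chemokine receptor CCR6 at 6.71 ± 4.14 and 5.85 ± 0.83. The members of smallest p went opposite ways: BATF was at 8.62 ± 7.39 and 14.9 ± 2.93 FPKM, and STAT3 at 21.9 ± 6.02 and 15.7 ± 4.50. Of the 26 Th17 genes listed, 17 were in the table, and IL17F, IL22 and IL23R were not among them. Th1 genes differed by 0.01 (exact permutation p = 0.966), Th2 genes by -0.03 (exact permutation p = 0.894) and regulatory T cell genes by 0.05 (exact permutation p = 0.782). IFNG was at 204 ± 369 and 110 ± 203 FPKM, TBX21 at 16.2 ± 20.1 and 11.6 ± 7.79, GATA3 at 9.12 ± 3.14 and 9.32 ± 3.15, IL4 at 1.42 ± 1.03 and 2.82 ± 2.09, and FOXP3 at 11.6 ± 6.71 and 15.3 ± 6.23. Of these genes CCR6, IFNG and TBX21 had a lower mean FPKM with NR but log2 fold changes of 0.02 (SE 0.30), 0.08 (SE 1.21) and 0.08 (SE 0.54), none of which differs from 0 by more than its SE. HAVCR2, IL18R1, IL4R, TNFRSF18 and F5 had log2 fold changes of -0.45, -0.28, -0.66, 0.76 and -0.56.

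Arginine, urea cycle and polyamine genes did not differ as a list (-0.0056, 95% interval -0.31 to 0.30, exact permutation p = 0.968), and 1 of 23 members had a p under 0.05 adjusted over the list alone. That member was OAZ1, the antizyme that restrains polyamine synthesis, at 64.5 ± 13.7 FPKM in placebo and 92.6 ± 12.7 with NR. ASL, argininosuccinate lyase, was at 2.39 ± 0.63 and 3.32 ± 0.75 FPKM (log2 fold change 0.35, SE 0.14, adjusted p = 0.221), and ARG2 at 6.05 ± 2.96 and 6.05 ± 1.74 (log2 fold change 0.09, SE 0.28). Of the 37 arginine, urea cycle and polyamine genes listed, 23 were in the table, and ASS1 was not among them. Targets of NRF2, the transcription factor of the oxidative stress response, differed by 0.09 (95% interval -0.14 to 0.31, exact permutation p = 0.427). Of 26 members, 2 had a p under 0.05 adjusted over the list alone. These were TKT, a transketolase (6.39 ± 1.28 and 9.62 ± 2.02 FPKM), and GSTP1, a glutathione transferase (13.8 ± 2.88 and 21.8 ± 6.35 FPKM). HMOX1 was at 4.43 ± 7.27 and 2.84 ± 2.56, GCLM at 5.33 ± 1.48 and 7.29 ± 3.27, TXNRD1 at 19.6 ± 13.5 and 14.6 ± 6.17, NFE2L2, which encodes NRF2, at 30.99 ± 8.06 and 24.4 ± 10.7, and its inhibitor KEAP1 at 5.60 ± 1.07 and 6.93 ± 1.06 FPKM. Of the 33 NRF2 targets listed, 26 were in the table, and NQO1 was not among them.

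The naive and central memory list differed by -0.21 (95% interval -0.47 to 0.06, exact permutation p = 0.114), and NELL2, at 28.2 ± 8.78 FPKM in placebo and 15.7 ± 3.84 with NR, was its 1 member past 0.05 adjusted over the list alone. The effector memory and cytotoxic list differed by 0.21 (exact permutation p = 0.602), and GZMM was its 1 such member. Type I interferon genes differed by -0.23 (95% interval -0.76 to 0.25, exact permutation p = 0.402); 27 of 36 members had a negative fold change, and STAT2 and IFIT5 had log2 fold changes of -0.57 and -0.49. Without the placebo donor of highest mean this list differed by -0.05 (exact permutation p = 0.743). In the autophagy and lysosome list (-0.01, exact permutation p = 0.806) the 1 member past 0.05 adjusted over the list alone was GABARAPL1, at 21.8 ± 10.3 and 8.96 ± 4.71 FPKM. Heat shock genes differed by -0.13 (exact permutation p = 0.315), with HSPD1 at -0.50 and HSPH1 at -0.49. Circadian clock genes differed by 0.06 (exact permutation p = 0.313), with BMAL1 at -0.33 and NR1D1 at 0.46. Immediate early and activation genes differed by 0.13 (exact permutation p = 0.780), with JUNB at 0.97 and KLF6 at -0.96, and NF-kB and inflammatory cytokine genes by 0.08 (exact permutation p = 0.686), with RELB at 0.87 and PYCARD at 0.55. The T cell receptor signalling list differed by -0.02 (exact permutation p = 0.734), with PTPRC at -0.44, and CD4 itself was at 57.3 ± 15.6 and 54.0 ± 10.9 FPKM.

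Among metabolic lists, the tricarboxylic acid cycle differed by 0.02 (exact permutation p = 0.724), with IDH3G at 0.44 and MDH2 at 0.33, and glycolysis by -0.00096 (exact permutation p = 0.993), with SLC2A3 at -0.67 and PFKL at 0.36. Fatty acid oxidation and PPAR genes differed by 0.03 (exact permutation p = 0.627), with ACADS at 0.40 and ETFB at 0.42, and cholesterol synthesis by -0.04 (exact permutation p = 0.624), with PMVK at 0.48. Mitochondrial quality control and biogenesis genes differed by 0.0021 (exact permutation p = 0.966), with CLPP at 0.40 and POLRMT at 0.46. The unfolded protein and amino acid response list differed by 0.0069 (exact permutation p = 0.976), with SDF2L1 at 0.63 and EDEM1 at -0.50, the glucocorticoid response by 0.02 (exact permutation p = 0.859), with KLF9 at 0.17 and SMAP2 at -0.09, and the cell cycle by 0.06 (exact permutation p = 0.527), with E2F1 at 0.27 and ZWINT at -0.29. Only 3 of 41 replication dependent histone genes were in the table, too few for a test of the list; H2BC12 and H1-2 had log2 fold changes of 0.41 and 0.57, both under 0.05 adjusted over the list alone.

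Markers of other blood cells were few and variable. B and plasma cell genes differed by 0.43 (95% interval -0.36 to 1.23, exact permutation p = 0.253, 7 of 22 listed genes in the table), with IGHA1 at 7.47 ± 7.52 FPKM in placebo and 18.7 ± 18.8 with NR and CD74 at 74.1 ± 40.7 and 87.3 ± 26.7. Monocyte genes differed by 0.22 (exact permutation p = 0.470, 6 of 20 in the table), with S100A9 at 1.60 ± 1.79 and 2.95 ± 2.30 FPKM and CST3 at 2.05 ± 1.98 and 2.60 ± 0.98. CD8 and NK cell genes differed by -0.18 (exact permutation p = 0.702, 6 of 20 in the table), with CRTAM at -0.74 and FCER1G at -0.24. The dendritic, erythroid and neutrophil and basophil lists had 3, 2 and 2 members in the table and the platelet list had 0, so these lists were not tested.

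Over the whole profile, the groups accounted for 11.8% of the squared distance between donors (exact permutation p = 0.0528). Principal components 1, 2 and 3 held 23.8%, 19.97% and 14.3% of the variance. Placebo and NR donors differed on component 2 (exact permutation p = 0.0457) and component 3 (exact permutation p = 0.0255), but not after adjustment over the 3 components (adjusted p = 0.0685 for each, exact permutation test). The sum of FPKM was 235780 ± 16976 in placebo and 260960 ± 30498 with NR (exact permutation p = 0.0662, adjusted p = 0.321 over 9 technical measures). The mitochondrial share was 19.9% ± 4.99 and 23.3% ± 6.91 (exact permutation p = 0.278), and the rank correlation of a donor's deviations with transcript GC content averaged -0.12 ± 0.16 and 0.11 ± 0.28 (exact permutation p = 0.0713). The sample numbers in the column names lie in separate ranges for placebo and NR, and no batch or date is given, so an effect of processing order cannot be told apart from the group.

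**Figure D3:**
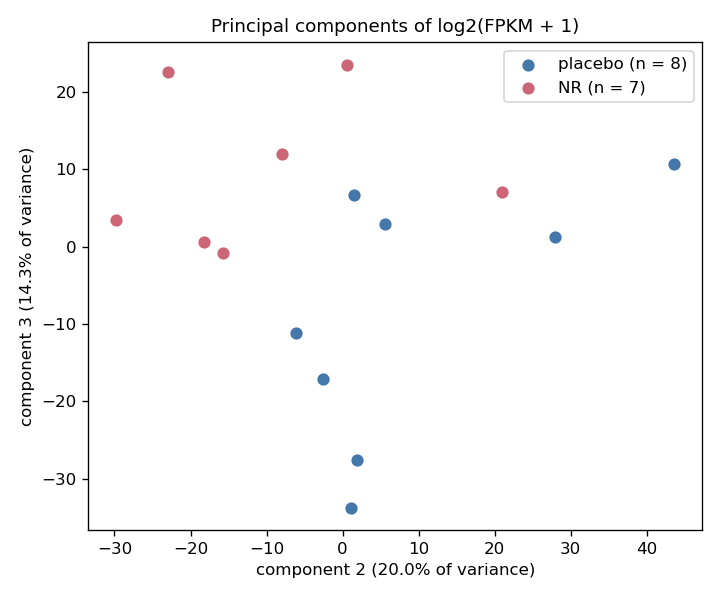
Principal components 2 (19.97% of the variance) and 3 (14.3%) of log2(FPKM + 1) for the 15 donors, with placebo (n = 8) and NR (n = 7) by colour. The groups lie apart in part and overlap, with an adjusted p of 0.0685 on each component by exact permutation.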

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

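The mean of each of 32 lists, the FPKM of SNHG19 and PARGP1 and 9 technical measures were tested within each group for a donor far from the others, by the gap to the nearest donor divided by the range of the group. Of 86 groups tested 4 stood out, and chance flags about 4.3. All 4 were lists in the placebo group, and in 3 of them (all but interferon) it was the same donor, placebo replicate 5, which was also the highest of all donors on principal component 2. So the 4 are not separate events, and the number expected by chance is no measure for them. The gap was 0.704 of the range for the lowest donor in NAD synthesis and transport, 0.612 for the highest donor in the type I interferon response, 0.535 for the lowest donor in immediate early and activation genes and 0.538 for the lowest donor in heat shock genes. The donor far from the others was then left out of each list, placebo replicate 2 for interferon and placebo replicate 5 for the other lists. The differences between the groups went from -0.03 to -0.07, from -0.23 to -0.05, from 0.13 to -0.14 and from -0.13 to -0.20, in the same order, with an exact permutation p of 0.255, 0.743, 0.543 and 0.0390, not adjusted for the lists.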

How the results depend on the processing

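Removal of GC content and length trends, rescaling to nuclear protein coding genes, the mitochondrial covariate and leaving out 2 NR donors were chosen after the data were seen. The number of genes past the threshold (2) was 1 (SNHG19) with a mean of 5 FPKM or more, where fewer genes (5988) were tested and PARGP1 was not, and 1 (PARGP1) with TPM. It was 0 with median of ratios scaling, quantile normalization, the naive covariate, rescaling to nuclear coding genes, the mitochondrial covariate, and without the 2 NR donors of highest mitochondrial share. Exact permutation per gene gave 0 too, but it is no check of 2 genes, since at least 32 genes must pass together before it can call any. The count was 883 with array weights and 0 to 364 with 1 donor left out (364 without NR replicate 1), 3 with GC and length trends removed (SNHG19 and 2 others, without PARGP1) and 2 elsewhere; the cause was not tested. The 1737 genes at an unadjusted p under 0.05 became 1123 with the stricter filter, 958 without the 2 NR donors, where fewer samples were tested, and 2830 with array weights, and ranged from 1273 to 2361 with 1 donor left out. Lists past the threshold stayed at 0 except for 4 with preset camera and 1, oxidative phosphorylation, by fry for change in either direction. The whole profile share of 11.8% passed 0.05 at 12.7% with TPM (exact permutation p = 0.0440), 11.9% with median of ratios (exact permutation p = 0.0496) and 12.4% with nuclear coding totals (exact permutation p = 0.0426). It was 9.97% with GC and length trends removed (exact permutation p = 0.131), 9.04% with the mitochondrial covariate (exact permutation p = 0.159), 9.96% without the 2 NR donors (exact permutation p = 0.251), and its p stayed above 0.05 in the other settings with all donors. It ran from 10.5% to 14.9% with 1 donor left out (exact permutation p from 0.0157 to 0.145). SNHG19 stayed higher and PARGP1 lower in all settings that tested them. Omitting the filter removed or added no gene and is no check. Depth is unknown, so its limits could not be weighed. No paired analysis was possible because the groups are different donors.

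Of 862 comparisons of a list difference with its value under an alternative, 124 changed sign, and of 3174 such comparisons of a named gene, 100 did. None of these lists or genes had passed the threshold, and in 122 and 99 of them the value as reported lay within 1 SE of 0; the cause was not tested. The values on the log2 scale were as follows. With a pseudocount of 0.1 the sign changed for Th2 0.076, Arginine 0.021 and HMOX1 0.23. With a pseudocount of 0.5 the sign changed for Th2 0.0092, Arginine 0.0045 and HMOX1 0.069. With a mean of 5 FPKM or more the sign changed for Mitochondrial quality control -0.019, Glycolysis 0.015, Fatty acid oxidation and PPAR -0.014, Glucocorticoid response -0.0074, Unfolded protein response -0.021 and Cell cycle -0.012. With TPM, which lowered the median of all genes, the sign changed for Th1 -0.12, Treg -0.086, NRF2 targets -0.031, Antioxidant enzymes -0.0081, NF-kB -0.028, Immediate early and activation -0.0012, Mitochondrial quality control -0.13, Tricarboxylic acid cycle -0.12, Fatty acid oxidation and PPAR -0.092, Circadian clock -0.058, Glucocorticoid response -0.095, Unfolded protein response -0.097, Cell cycle -0.051, ARG2 -0.011, BPGM -0.11, TBX21 -0.021, GATA3 -0.10, CD38 -0.10, IFNG -0.029, SIRT3 -0.11, CCR6 -0.078 and HMOX1 0.029. With median of ratios scaling the sign changed for NAD synthesis and transport 0.015, Th2 0.023, Arginine 0.050, Glycolysis 0.056, Cholesterol synthesis 0.0077, Autophagy and lysosome 0.040, T cell receptor signalling 0.038, NAMPT 0.049 and HMOX1 0.035. With quantile normalization the sign changed for NAD synthesis and transport 0.0047, Arginine 0.035, Glycolysis 0.0052, Autophagy and lysosome 0.030, NAMPT 0.044 and HMOX1 0.00071. With the naive covariate the sign changed for Th1 -0.20, Treg -0.017, Effector memory and cytotoxic -0.13, NF-kB -0.053, Immediate early and activation -0.037, Mitochondrial quality control -0.0096, Autophagy and lysosome 0.015, Unfolded protein response -0.12, CD4 0.015, GATA2 -0.0090, TBX21 -0.33, IFNG -0.71, CCR6 -0.038 and HMOX1 0.022. With GC and length trends removed the sign changed for Th2 0.0020, Arginine 0.0060, Autophagy and lysosome 0.0020, NAPRT -0.19, SMAP2 0.078, SIRT1 0.029, GATA2 -0.16, TBX21 -0.13, SIRT3 -0.071 and NAMPT 0.052. With nuclear coding totals the sign changed for Th1 -0.038, Mitochondrial quality control -0.051, Tricarboxylic acid cycle -0.037, Fatty acid oxidation and PPAR -0.023, Glucocorticoid response -0.032, Unfolded protein response -0.044, BPGM -0.032, GATA3 -0.024, CD38 -0.027, SIRT3 -0.036 and CCR6 -0.036. With the mitochondrial covariate the sign changed for Th1 -0.00075, Th2 0.047, Glycolysis 0.017, Autophagy and lysosome 0.0080, Glucocorticoid response -0.012, Unfolded protein response -0.025, T cell receptor signalling 0.0090, SIRT3 -0.052 and NAMPT 0.021. Without the 2 NR donors the sign changed for Th2 0.071, Mitochondrial quality control -0.017, Glycolysis 0.0031, Autophagy and lysosome 0.011, Unfolded protein response -0.066, T cell receptor signalling 0.010, CD4 0.035, ARG2 -0.019, GATA2 -0.053, TBX21 -0.062 and SIRT3 -0.061. With 1 donor left out, the ranges that cross 0 were Th2 -0.11 to 0.078, Arginine -0.093 to 0.049, Glycolysis -0.066 to 0.030, Glucocorticoid response -0.055 to 0.063, CD8 and NK -0.39 to 0.060, CD38 -0.086 to 0.082, SIRT3 -0.046 to 0.092, NAMPT -0.16 to 0.13, Th1 -0.13 to 0.18, Treg -0.028 to 0.15, Mitochondrial quality control -0.025 to 0.022, Unfolded protein response -0.14 to 0.073, ARG2 -0.100 to 0.21, BPGM -0.039 to 0.11, TBX21 -0.15 to 0.41, IFNG -0.57 to 0.78, CCR6 -0.21 to 0.19, HMOX1 -0.23 to 0.40, GATA3 -0.092 to 0.17, Immediate early and activation -0.14 to 0.24, Autophagy and lysosome -0.038 to 0.011, T cell receptor signalling -0.055 to 0.0024, CD4 -0.14 to 0.014, GATA2 -0.059 to 0.20, Tricarboxylic acid cycle -0.012 to 0.041, NAD synthesis and transport -0.073 to 0.013, Fatty acid oxidation and PPAR -0.0069 to 0.054, Effector memory and cytotoxic -0.017 to 0.38 and NF-kB -0.019 to 0.17.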

Other observations

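Gene types, symbol families and chromosomes were scanned after the data were seen, and the tests of the unadjusted counts and of naive cells below were also chosen after the result was seen. Of 15 gene types with at least 15 genes, 4 passed an adjusted p of 0.05 by exact permutation of the mean. Miscellaneous RNA genes, all 15 of them copies of the 7SL and 7SK RNAs, were lower with NR by -0.61 on the log2 scale (exact permutation p = 0.000155, the smallest the test can give, adjusted p = 0.0023). All 15 had a negative fold change, and the mean of every NR donor lay below the placebo median. RN7SL2 was at 75.2 ± 61.6 FPKM in placebo and 26.6 ± 17.4 with NR, RN7SL1 at 40.03 ± 35.1 and 15.7 ± 6.61, and RN7SL809P at 4.07 ± 1.94 and 1.24 ± 0.92. The difference ran from -0.90 to -0.56 over 6 scalings, and it passed in 15 of 15 runs with 1 donor left out. Copies of the same RNA share sequence, so the genes are not 15 separate pieces of evidence. The RN family, which also holds the snRNA gene RN7SK, was the 1 of 77 symbol families to pass (-0.59, exact permutation adjusted p = 0.012).

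Mitochondrial tRNA genes were higher by 0.68 (21 genes, 20 with a positive fold change, exact permutation adjusted p = 0.0326), with MT-TC at 3.88 ± 3.15 and 10.8 ± 5.03 FPKM and MT-TQ at 2.67 ± 1.99 and 9.53 ± 4.56. They passed in 4 of 15 runs with 1 donor left out, where the difference ran from 0.61 to 0.84. The difference was 0.63 with nuclear coding totals (exact permutation adjusted p = 0.0594) and 0.82 with GC and length trends removed (exact permutation adjusted p = 0.0408). T cell receptor joining segments were lower by -0.50 (56 genes, 31 lower and 1 higher at an unadjusted p under 0.05, exact permutation adjusted p = 0.0326), and snRNA genes by -0.32 (exact permutation adjusted p = 0.0326). Whether the genes within a type vary independently was not tested, so these counts of genes are not separate pieces of evidence. The segments passed in 8 and the snRNA genes in 6 of 15 runs with 1 donor left out, and the snRNA genes had an adjusted p of 0.0597 with median of ratios scaling (exact permutation). With GC and length trends removed these became -0.21 (exact permutation adjusted p = 0.242) and -0.12 (exact permutation adjusted p = 0.308). Chromosome 19, whose genes had the highest median GC content shown here (58.8%), was higher by 0.12 (726 genes, exact permutation adjusted p = 0.0972) and by 0.028 with GC and length trends removed (exact permutation adjusted p = 0.0946), and 0 of 22 chromosomes passed.

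The counts of genes were set against 100 splits of the 15 donors into 7 and 8, the real split included. For genes past the threshold, 2 splits gave 2 or more, and the highest other split gave 623. For genes at an unadjusted p under 0.05, 3 splits gave 1737 or more, and the highest other gave 2338. Both shares are under 0.05, but whether chance is excluded is borderline: their 95% exact binomial intervals (0.243% to 7.04% and 0.623% to 8.52%) include 5%, and in an earlier, smaller draw of splits with another seed the share for the unadjusted count was above 0.05. A split with 623 genes points to a structure of the donors that was not identified; its group of 7 held 5 of the 7 NR donors, so it overlaps the treatment groups. With GC and length trends removed the count was 1386, above the 95th percentile of the other splits (1287), but 5 of 100 splits gave as many (highest other 2741), so part of the excess could come from GC or length and this cannot be told apart. The criterion first written, the percentile alone, would have excluded GC and length as the cause; the share of splits was added to it after the count was seen. Rescaled to nuclear coding genes, for which no other splits were run, the count was 1878 and did not fall. That argues only against a scaling of all genes by the mitochondrial share of the FPKM total as the cause. The count was 1203 with that share as covariate and 958 without the 2 NR donors of highest share, where fewer samples were tested. So whether part of the excess goes with the share cannot be told apart.

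The higher means of oxidative phosphorylation and ribosomal protein genes were set against 2 explanations. The first was that short or abundant transcripts were higher in general. Among 10000 random lists matched on length, GC content and level, the oxidative phosphorylation list was at percentile 100 (0.20 against 95% of lists from -0.10 to 0.01). The median of its matched lists was -0.05, so matched genes were not higher in general, which argues against this explanation for that list. The random genes were drawn one by one, so the range leaves out correlation between genes and spread between donors. The percentile is therefore no test of the difference between the groups. The ribosomal list was at percentile 100 too, but its median level on the log2 scale (8.38) was far above that of its matched genes (5.74), so for it abundance cannot be told apart. The second was fewer naive cells with NR. With the index of naive against effector markers as covariate, the differences kept 0.937 (oxidative phosphorylation) and 0.983 (ribosomal) of their size. The index itself differed between the groups by -0.42 (exact permutation p = 0.386). Its effector list varied more between placebo donors (SD 0.77) than its naive list (SD 0.23). So the values argue against a shift along this index, but they cannot decide on naive cells alone. Since neither list passed after adjustment, a chance difference, fewer naive cells and an order of processing stay open. An effect of NR is a hypothesis that was not tested further.

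For PARGP1, reads moving between it and its parent gene may be a candidate explanation. PARG was not higher with NR but at a log2 fold change of -0.22 (SE 0.14, 3.83 ± 1.04 FPKM in placebo and 3.13 ± 0.76 with NR), which argues against a shift of reads to PARG. The sum of both differed by -0.51, but it includes the fall of PARGP1 itself. FPKM are scaled to transcript length, so such a sum need not keep the number of reads. Other near copies of PARG were not tested.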
